A study of Homo sapiens with 2 samples.

How the data were processed

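Gene expression was measured in KYSE150, an established human esophageal squamous cell carcinoma line, with 2 PrimeView arrays, Affymetrix 3'-type expression arrays that carry 1 biotin-labelled sample each. One array held RNA from cells with the vector control and the other RNA from cells infected with lentivirus for L1CAM small hairpin RNA, so each group had 1 array and there was no replicate of either. Per the labels' protocols, cells were passaged or harvested after infection, RNA was extracted with TRIzol and RNeasy columns with DNase digestion, and a single round of amplification was used for labelling. The series text describes the control as an empty plasmid and the treatment protocol lists a control shRNA virus; the sample labels give only "vector control", and that name is used here.

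The deposited values were log2 expression values per probe set, made by the authors with RMA and Partek per the submitters' processing notes; the versions and the probe set definition are not given in the sources used here. RMA corrects background, normalizes arrays by quantiles and summarises the probes of a probe set on the log2 scale. It pulls low values together, so differences of dim genes can be understated. The table held 49293 probe sets. The log2 medians were 7.53 for the control and 7.57 for the knockdown array, and after sorting the columns differed by at most 0.0621, so the arrays had been brought to nearly one distribution before deposit. Scanner files and detection calls were not used here, and the precision is limited by the number of arrays.

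Gene names came from the platform annotation given with the series. Of the probe sets, 44988 had 1 gene symbol, 1832 had several and 2473 had none; only the first kind entered the gene comparison. Of those 44988, the Entrez number of 44961 was found in a RefSeq gene table of assembly GRCh38.p14, which was used for names only. They covered 18132 genes. No build is stated for the array, so no coordinates are given.

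The difference of a gene was its log2 value in the knockdown array minus that in the control array, as deposited. The probe set with the highest mean over both arrays stood for its gene. A gene was kept if that probe set reached the array median in at least 1 array, which left 10709 genes. A dim gene can thus pass only through the array where it is higher. Examples named below are SPARC (6.95 in the control array), S100A8 (7.08), AKR1B10 (7.20) and STARD4 (7.30), all below the control median. Their differences are less certain. Values of list members are from the brightest probe set unless stated, and other probe sets of several members went the opposite way. With 1 array per group no test across replicates, standard error or p-value can be given, so a fixed limit of 2-fold was used. As a measure of technical spread, the pooled SD of the difference among probe sets of the same gene was 0.303 over the 6220 genes with several probe sets past the filter. Probe sets of one gene can share probes and come from the same RNA, so this spread leaves out any variation between cultures. The SD of the difference over all genes past the filter was 0.261, no larger than the spread among probe sets of one gene. Several list members named below lie within that spread.

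A set of 37 gene lists was fixed before the data were examined, as were the level filter, the gene summary, the fold limit and the naming rule. Of their 755 genes, 702 had a single-gene probe set; the others are not analysed here. Each list's median difference was placed among the medians of 10000 random lists of the same size drawn from 20 bins of mean level, and a list below percentile 2.5 or above 97.5 is described as apart from random lists. A list with fewer than 5 genes past the filter got values only. These percentiles describe this pair of arrays. Genes are not replicates, and genes that vary together make such percentiles more extreme than independent genes would.

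The naming rule took L1CAM with every probe set, the 15 genes with the largest increase and the 15 with the largest decrease whose other probe sets did not go the opposite way by more than 0.3, up to 4 members of each list past the filter with the largest change (at least 0.58 where there were any), and EZR, ITGB1, FOS and JUN. Genes without a proper symbol were replaced by the next. Where fewer than 4 members of a list reached 0.58, the next largest were named too in many lists, which was decided after their values were seen. Other lists are given with fewer named members or none. The rule looked only at probe sets past the filter, and for genes named here whose other probe sets went the opposite way below it, examples are given beside them. A gene that met the rule is not reported here (1 gene). Alternatives were centring on the median, quantile normalization, a lowess correction over level (span 0.2), other level filters, other gene summaries, fold limits of 1.5 and 3, the mean in place of the median of a list, unmatched random lists and lists without genes held by several lists. The dimmest probe set of a gene, the omission of probe sets ending in _x_at (which share probes with other sequences), the cholesterol list without DHCR7, the difference relative to the median gene and the 3 immune lists on only genes with several probe sets were added after the data had been seen. The planned check on spike-in and 3'/5' control probe sets was not run, because the values used here held 0 probe sets with the AFFX prefix. The planned check on seed matches of the stated silencing RNA was not run, because it needs transcript sequences that were not used here.

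The procedures were tested on simulated data made for this comparison from the real levels, with noise of SD 0.15 per array among the 10701 genes of that step. That noise is per array, whereas the spread of 0.303 among probe sets of one gene is that of a difference. The simulated differences of unchanged genes still varied less than that spread. In the real arrays recovery would therefore be poorer and false calls more likely. Of 100 genes changed by 1.2 on the log2 scale 90 were recovered, and of 100 changed by 1.5, 99. No unchanged gene was called (0 calls), but noise this small hardly reaches the 2-fold limit. That outcome was therefore fixed in advance and gives no rate of false calls for the real arrays. Of 200 random lists of 20 genes with no shift, 3.5% fell outside the limits, and 100% of 50 lists shifted by 0.3 were found. Both outcomes were also fixed in advance. The unshifted lists were drawn at random like the lists they were ranked among, and the shift was large against noise this small. Neither outcome covers lists whose genes vary together. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and plots used matplotlib 3.10.9.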

Results

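Total RNA of KYSE150 cells was profiled on 2 arrays to compare cells given L1CAM small hairpin RNA with vector control cells. L1CAM is a transmembrane cell adhesion molecule of the immunoglobulin superfamily. Each group had 1 array, so all values below are single measurements without a replicate error, and "knockdown array" means the array labelled L1CAM knockdown. Differences are log2 values, knockdown minus control. Values ran from 2.58 to 15.15 in the control and from 2.53 to 15.14 in the knockdown array, and the arrays correlated across all probe sets with r = 0.991, where probe sets are not independent replicates.

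L1CAM was measured by 2 probe sets, which gave different answers. The brighter one read 11.2 in the control and 10.7 in the knockdown array, a difference of -0.58, or 33.1% less signal. Of all probe sets past the level filter, 2.54% had a lower difference. The dimmer one read 7.74 and 7.77, a difference of 0.04, at percentile 60.7 and only just above the filter level. The mean over both probe sets was -0.27 with an SD of 0.436, and a spread of 0.303 was usual among probe sets of one gene. The direction given by the label was seen in 1 of the 2 probe sets.

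Among the 10709 genes past the level filter, 19 were at least 2-fold higher and 3 at least 2-fold lower in the knockdown array. Together they made up 0.205% of the genes. The central 95% of genes lay between -0.58 and 0.42, with a median of -0.11. That median was -0.04 with the mean of a gene's probe sets and -0.05 with no level filter. At a limit of 1.5-fold 109 genes were higher and 248 lower, a split of 30.5% higher. That split moved with the scaling, to 32.9% after quantile normalization, 44.4% after centring, 49.5% after a lowess correction over level and 69.4% relative to the median gene, so no direction is drawn from it. At 2-fold the higher share was 86.4% as deposited and between 87.0% and 97.0% under those 4 scalings, the last being relative to the median gene with 32 genes higher and 1 lower.

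The largest differences of the deposited values were those of DHCR7, the last enzyme of cholesterol synthesis, at 11.7-fold higher (5.39 to 8.95), and UBB, a polyubiquitin gene, at 8.58-fold higher in the brighter of 2 probe sets (6.66 to 9.77). Both control values lay below the median of that array (7.53), and that of DHCR7 also below its 25th percentile (5.90), so these folds are not exact. Each rested on few probe sets: DHCR7 had 1, and both of UBB's were of the _x_at kind, which can also detect related ubiquitin genes. In 10 of the 19 genes the control value lay below the median level of that array, where differences are less certain. F2R, the thrombin receptor, was 3.33-fold higher. S100A9, a calcium-binding alarmin of squamous and myeloid cells, was 3.26-fold higher, and NNMT, nicotinamide N-methyltransferase, 3.06-fold. RSAD2, the antiviral protein viperin, was 2.99-fold higher with its second probe set at 1.28 on the log2 scale. AKR1C2, an aldo-keto reductase, was 2.87-fold higher, but it has a near-identical paralog in AKR1C1, so the assignment is uncertain, and its 2 probe sets below the filter read -0.10 and -0.29. IGFBP3, an insulin-like growth factor binding protein, was 2.59-fold higher in a probe set of the _x_at kind, but its other probe set, below the filter, read -0.21. AP1S3, an adaptor complex subunit, was 2.55-fold higher.

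TGFBI, a matrix protein induced by TGF-beta, was 2.38-fold higher, and its 4 probe sets ranged only from 1.13 to 1.25. LYPLA1, an acyl-protein thioesterase, was 2.11-fold higher in the brighter of 2 probe sets. TGFB2, the growth factor TGF-beta 2, was 2.09-fold higher, but its other probe set gave 0.22. OLR1, an oxidized lipoprotein receptor, was 2.06-fold higher. PMAIP1, the pro-apoptotic protein NOXA, was also 2.06-fold higher, with 0.39 in its second probe set. PLRG1, a spliceosome component, differed by 1.13 in its brightest probe set but was higher in only 2 of 4 probe sets, the lowest being -0.24. Of the 19 genes, 9 had 1 probe set past the filter and 10 had several. Among those 10, all probe sets went the same way in 8 genes and all passed 2-fold in 4.

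At the 2-fold limit 3 genes were lower. ZNF680, a zinc finger gene, was 3.05-fold lower by its probe set past the filter, while one below the filter read 0.36. ZFP30, another zinc finger gene, was 2.16-fold lower in a probe set of the _x_at kind, with probe sets below the filter at -0.14 and 0.70. The knockdown values of these 2 genes, 6.72 and 6.74, lay below the median level of that array (7.57), so their folds are not exact either. PTGS1, the constitutive cyclooxygenase, was 2.11-fold lower, with its 3 probe sets past the filter between -1.08 and -0.24. The remaining 12 genes of this group lay short of 2-fold. The first 6 were ZHX2 at -0.997, CEL at -0.99, TNRC6C, a component of the RNA silencing complex, at -0.93, ZNF580 at -0.92, OBSL1 at -0.92 and FAM50B at -0.92. Both CEL probe sets were of the _x_at kind, which share probes with other sequences. Other probe sets of TNRC6C, below the filter, read 0.0247 and 0.25, and the weakest OBSL1 probe set past the filter read -0.35. SSBP3 read -0.90, with probe sets below the filter at 0.23 and -0.0488, and SOX2, the squamous lineage transcription factor, read -0.90 with its second probe set at -0.77 and one below the filter at 0.25. NFKBIB, an inhibitor of NF-kB, read -0.89, but 2 of its 4 probe sets read -0.12 and -0.14. DNM3 read -0.88. NFIC read -0.88 in its brightest probe set and was lower in 9 of 10, with a median of -0.33 over them. USB1 read -0.88, with others past the filter at -0.44 and -0.55.

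**Figure D1:**
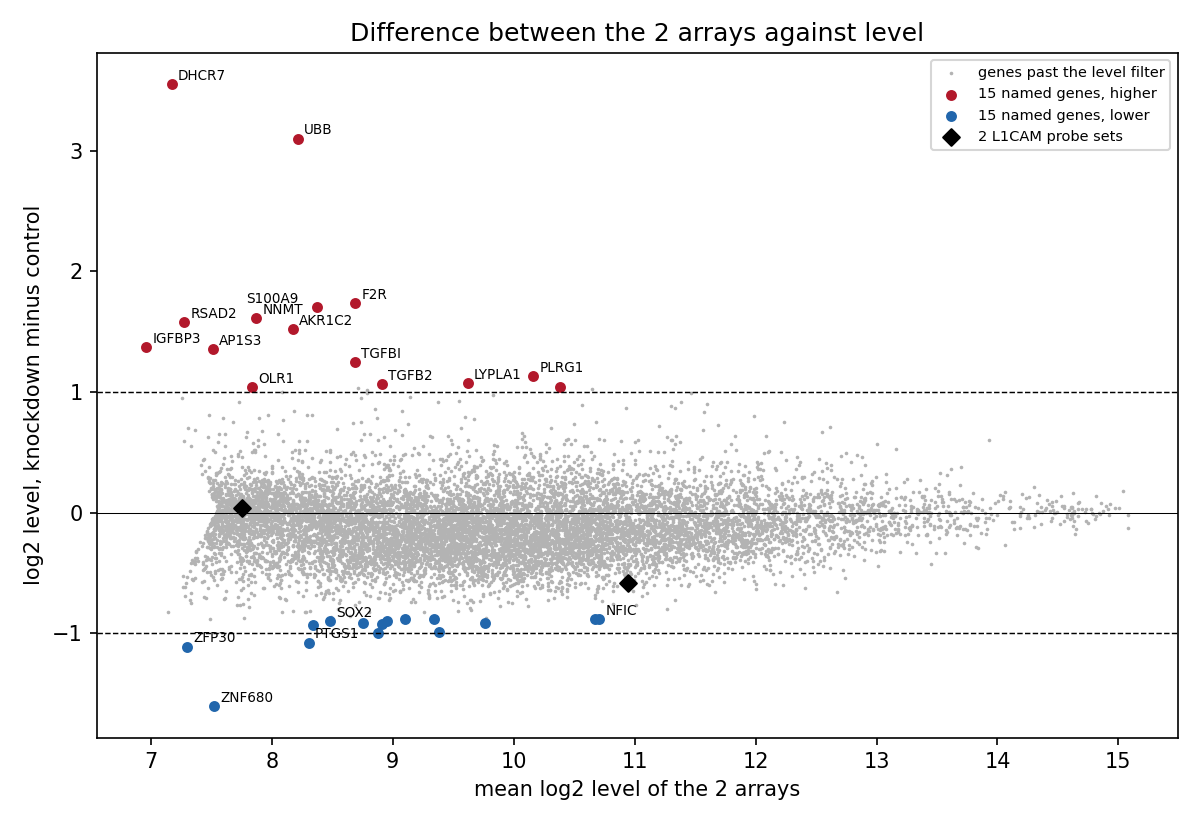
Difference between the 2 arrays (log2, knockdown minus control) against the mean log2 level of the 2 arrays, 1 grey point per gene past the level filter; red and blue points are the 15 named genes in each direction, black diamonds the 2 L1CAM probe sets and dashed lines 2-fold. DHCR7 (3.55) and UBB (3.10) stand above all other named genes, while the L1CAM probe sets lie at -0.58 and 0.04.

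Of the 37 gene lists, 36 had enough members for a percentile. Of these, 10 lay above and 2 below level-matched random lists, where 1.8 are expected by chance if genes vary independently. Genes of one list can vary together, so more than that can fall outside without any effect of the knockdown. Under each of 13 alternatives 5 of the 12 stayed on their side. These were the lists of interferon-stimulated genes, antigen presentation, NF-kB targets, cholesterol synthesis and the endoplasmic reticulum and amino acid stress response. Not all 13 are independent checks. Centring shifts every gene alike and so cannot change a percentile. Quantile normalization could do little, because the 2 columns already had nearly one distribution.

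Interferon-stimulated genes, antigen presentation genes and NF-kB targets were higher in the knockdown array as groups. For the interferon list the median of 23 members was 0.29, above all 10000 random lists; 4 members were at least 1.5-fold higher and 0 lower. The size depended on the filter, with a median of 0.16 with no filter and 0.13 with the filter on the mean of both arrays or without _x_at probe sets. Besides RSAD2 (1.58) these were IFITM1, a membrane restriction factor (0.96), DDX60 (0.92) and IFIH1, a cytosolic RNA sensor (0.74). Not all members were higher, and 8 of 23 lay below 0. The antigen presentation list had a median of 0.25 over 14 members, again above all 10000 random lists. B2M, the light chain of MHC class I, differed by 0.60 with 8 of 8 probe sets higher, the peptide-trimming enzyme ERAP1 by 0.48, the immunoproteasome subunit PSMB9 by 0.43 and HLA-C by 0.42, while HLA class I genes share similar sequences and cannot be fully separated by probes.

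The list of NF-kB targets and cytokines had the highest median of all lists, 0.39 over 16 members, with 12 above 0 and 2 at least 1.5-fold higher. The latter were the cytokine IL1B (0.63) and the chemokine CCL5 (0.59). The adhesion receptor ICAM1 differed by 0.54 and the feedback regulator TNFAIP3 by 0.48. Across the alternatives its median ranged from 0.24, with no filter, to 0.43.

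Cholesterol synthesis genes were higher in the knockdown array, with a median of 0.29 over 19 members and 6 members at least 1.5-fold higher. Besides DHCR7 (3.55), squalene epoxidase SQLE differed by 0.88, ACAT2 by 0.77 and the sterol carrier STARD4 by 0.75, while 5 members lay below 0. The median lay above all 10000 random lists, and was 0.13 with the filter at the 75th percentile (percentile 99.91). Without DHCR7, a setting chosen after its value was seen, the median was 0.24 over 18 members, still at percentile 100. The endoplasmic reticulum and amino acid stress list had a smaller median of 0.10 over 25 members, of which only XBP1, the unfolded protein response transcription factor (0.75), passed 1.5-fold. PSAT1, an enzyme of serine synthesis, differed by 0.51 with 8 of 8 probe sets higher, and CHAC1 by 0.46, whereas DNAJC3 differed by -0.45. XBP1 rested on 1 probe set, and 9 of the 25 members lay below 0. Endoplasmic reticulum members went both ways. HERPUD1 and DNAJB9 read 0.26, while PDIA4 read -0.13 and HSPA5 -0.13 in its brightest probe set, though HSPA5 was higher in 4 of 6. No stress of the endoplasmic reticulum is drawn from this list. This list, too, lay above all 10000 random lists, and its median reached 0.16 with the mean of all probe sets and 0.20 with the dimmest.

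Lists of TGF-beta targets, mesenchymal markers, matrix proteolysis, NRF2 targets and the AP-1 family also lay above random lists, but each came inside under at least 1 alternative. The TGF-beta list had a median of 0.09 over 17 members (percentile 99.8). TGFBI, TGFB2 and ID1 (0.60) were at least 1.5-fold higher and the basement membrane collagen COL4A2 was lower (-0.80). Without genes held by several lists its median was -0.05, at percentile 74.8, and with the median of probe sets it was 0.25. The mesenchymal list had a median of 0.20 over 9 members (percentile 99.9), led by TGFBI (1.25) and the matrix protein SPARC (0.70), with vimentin (VIM) at 0.28 and LOX at 0.21. SPARC had 1 probe set past the filter, which read 6.95 in the control array, below the median of that array. In the matrix proteolysis list (median 0.06 over 13 members, percentile 98.5) the collagenase MMP1 differed by 0.99, the sheddase ADAM10 by 0.86 and MMP13 by 0.67, while MMP2 differed by -0.42. Its median ran from 0.0048 with the filter at the 75th percentile to 0.32 with the median of probe sets.

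The NRF2 list had a median of 0.11 over 19 members (percentile 99.95), with AKR1C2 (1.52) and AKR1B10 (0.79) higher and AKR1C3 (-0.78) lower. The glutathione enzyme subunit GCLC read -0.34 in its brightest probe set but was higher in 2 of 3 probe sets. With the mean of all probe sets the NRF2 list lay at percentile 93.1. The AP-1 list had a median of 0.10 over 10 members (percentile 99.2), which turned to -0.04 without probe sets ending in _x_at. None of its members reached 1.5-fold (0 of 10). ATF3 differed by 0.34 and FOSL1 by -0.33. FOS was higher in 4 of 4 probe sets (0.28 on average, SD 0.0702) and JUN lower in 4 of 4 (-0.24, SD 0.0477). Probe sets of one gene come from the same RNA and can share probes, so these counts and SDs are not replication. The brightest probe set of JUN read -0.22, between the lower and upper quartiles of all genes past the filter (-0.28 and 0.0464). That of FOS read 0.24, above the upper quartile. No direction of JUN apart from that of all genes is drawn.

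Genes of the G1/S transition and DNA replication, and genes of the squamous basal layer, were lower in the knockdown array as groups. In the replication list 25 of 29 members lay below 0 and the median was -0.25 (percentile 0.04). The median of all genes was itself below 0 (-0.11), and 10 of the 29 members lay above it. Cyclin E1 (CCNE1) differed by -0.69, the phosphatase CDC25A by -0.65, E2F1 by -0.53 and the chromatin assembly factor CHAF1A by -0.52. The basal list had a median of -0.28 over 11 members (percentile 0.43), with SOX2 (-0.90) and the hemidesmosome integrin ITGB4 (-0.77) at least 1.5-fold lower and LAMB3 (-0.36) and DST (-0.33) next. Both calls depended on the probe set chosen for each gene. With the mean of all probe sets the replication list lay at percentile 12.6 (median -0.10) and the basal list at 55.3 (median -0.02). Genes of G2/M and mitosis, by contrast, lay among random lists, with a median of -0.10 over 30 members (percentile 47.2). CKAP2 read 0.61, CENPE -0.45, CDC25C -0.44 and BIRC5 -0.34, but BIRC5 was higher in 5 of its 8 probe sets past the filter. The difference between the replication and mitosis lists was not tested.

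Lists of the adhesion machinery lay among random lists. The L1 family and its partners had a median of 0.04 and a mean of -0.05 over 9 members (percentile 93.6). ANK3, an ankyrin, read -0.63, L1CAM -0.58 in its brighter probe set, NRP1 0.40 and AP2M1 0.27. With no level filter the median of this list turned to -0.0835 (percentile 25.2). Integrins had a median of -0.21 over 9 members (percentile 17.8). ITGB4 read -0.77, ITGA3 -0.33, ITGA2 -0.31 and ITGB8 -0.24. ITGB1 differed by 0.13 in its brightest probe set, while its other probe sets past the filter ran from -0.15 to 1.23. Focal adhesion components had a median of -0.16 over 17 members (percentile 17.8), with FERMT1 at -0.45, BCAR1 at -0.43, TLN2 at -0.33 and TLN1 at -0.32. The list of ezrin, radixin, moesin and cortical linkers had a median of -0.19 over 11 members (percentile 13.9), with NF2 at -0.62, ICAM1 at 0.54 and RDX at 0.23. Ezrin (EZR) itself gave -0.24 in its brightest probe set and between 0.29 and 0.56 in the other 4, so its direction depended on the probe set. The medians of the last 3 lists turned above 0 with the mean of all probe sets, to 0.0316 for integrins, 0.0377 for focal adhesion and 0.0321 for ezrin and its kin, and also with the dimmest probe set. No direction is drawn for any of these 4 lists. Of the 24 lists inside the limits, 20 had a median that turned sign in at least 1 alternative.

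The ERK pathway output list had a median of -0.22 over 18 members and lay at percentile 6.97, inside the limits. EGR1 differed by -0.75, ETV4 by -0.54, DUSP5 by -0.42 and ETV5 by -0.39, though ETV5 was higher in 2 of 4 probe sets. The place of the list depended on the setting. With the level filter at the 75th percentile it lay at percentile 0.39 (median -0.33), and with the mean of all probe sets at 78.9 (median 0.0065). Epithelial junction genes had a median of -0.10 over 22 members (percentile 61.2), and of 0.0624 with the mean of all probe sets. PERP read 0.90, PKP3 -0.44, MARVELD2 -0.42 and PKP1 -0.38. The direction of PERP depended on the probe set, as its 3 past the filter ran from -0.68 to 0.90. Squamous terminal differentiation genes had a median of -0.04 but a mean of 0.10 over 14 members (percentile 59.1), and the median turned to 0.0031 after centring. With no level filter the list lay above random lists (median 0.0973, percentile 99.63). S100A9 read 1.71, S100A8 0.81 and SCEL 0.52, and the cornified envelope protein EVPL -0.82.

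Housekeeping groups and markers of other cell types were compared in the same way. Ribosomal protein genes had a median of 0.0054 and a mean of -0.0054 over 27 members (percentile 74.2), and the median turned to -0.0034 after quantile normalization and -0.0249 after the lowess correction; RPL13 read -0.31. Oxidative phosphorylation genes had a median of 0.01 over 29 members (percentile 92.9), with SDHD at 0.67 and NDUFV1 at -0.44. Proteasome genes had a median of -0.05 over 25 members (percentile 44.3) and heat shock genes of -0.12 over 14 (percentile 17.0). Common reference genes had a median of 0.04 and a mean of -0.03 over 13 members (percentile 93.8), and the median turned to -0.20 without _x_at probe sets. B2M read 0.60, POLR2A -0.60, PGK1 0.38 and IPO8 -0.34, but IPO8 was higher in 2 of 4 probe sets, by up to 0.85. Few markers of other cell types passed the level filter. Leukocyte markers had a median of 0.10 and a mean of -0.06 over 5 members (percentile 94.3), with CD68 at -0.61. Endothelial markers had a median of -0.0024 over 5 (percentile 62.9) and neural markers of -0.02 over 6 (percentile 84.0). The endothelial and neural medians turned above 0 after centring and after the lowess correction. With no level filter the endothelial list lay above random lists (median 0.12, percentile 98.08). The 1 fibroblast marker past the filter, ACTA2, read -0.56.

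**Figure D2:**
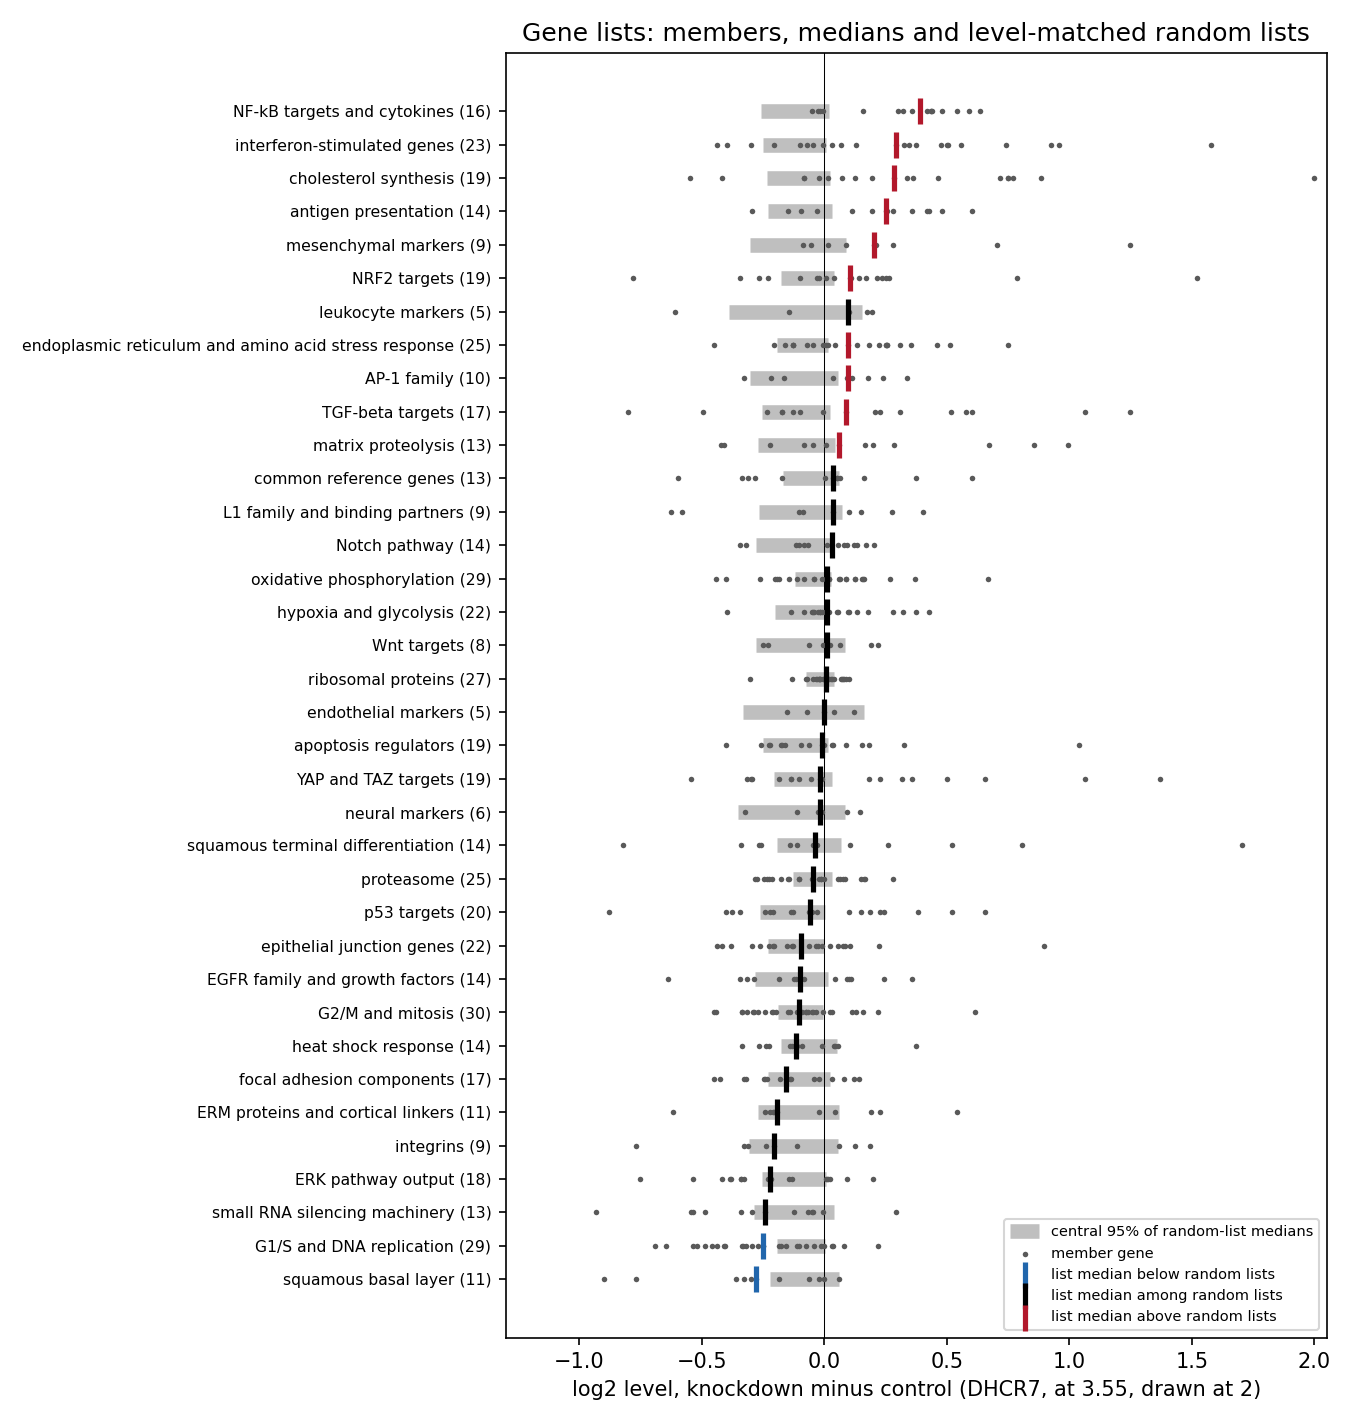
Log2 difference (knockdown minus control, x axis) for each gene list (y axis, number of members past the level filter in brackets); dots are member genes, vertical ticks list medians and grey bars the central 95% of medians of 10000 level-matched random lists. The NF-kB (0.39), interferon (0.29) and cholesterol synthesis (0.29) lists lie farthest above their grey bars, and the replication (-0.25) and basal layer (-0.28) lists lie below theirs.

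Probe sets of the same gene did not change alike. In 68.2% of the 6220 genes with several probe sets past the filter, the dimmest probe set had a higher difference than the brightest. It exceeded the brightest by at least 2-fold in 229 genes and fell short of it by as much in 14. For HIF1A the difference was 1.01 in the dimmest and 0.12 in the brightest probe set, for EIF4H 1.58 and -0.03, and for the ribosomal protein gene RPS6 1.54 and 0.04; these 3 genes were chosen as examples after their values were seen. Counting genes by the dimmest probe set gave 226 genes at least 2-fold higher and 12 lower, in place of 19 and 3. Of the 10 higher genes with several probe sets past the filter, 6 were also higher by the dimmest one.

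**Figure D3:**
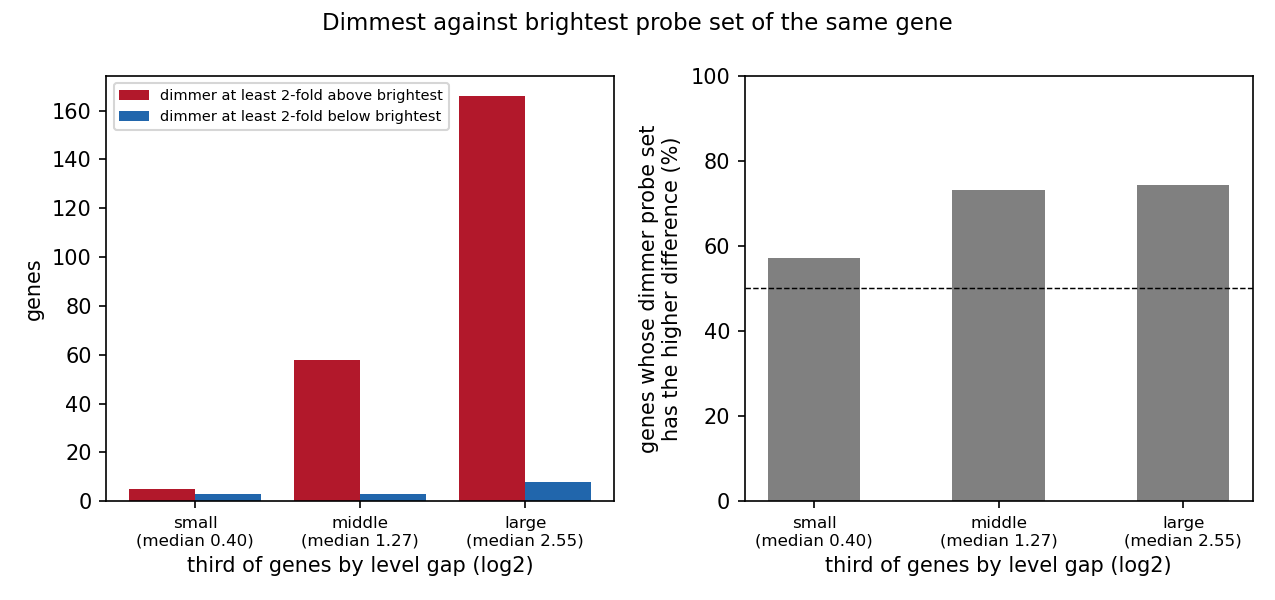
Genes in 3 groups of equal size by the log2 gap in level between their brightest and dimmest probe set; the left bars count genes whose dimmest probe set read at least 2-fold above (red) or below (blue) the brightest one in its difference between arrays, and the right bars give the percentage of genes whose dimmest probe set had the higher difference (dashed line, 50%). The count of the first kind goes from 5 to 58 to 166 genes with the level gap, and that of the second kind from 3 to 3 to 8.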

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

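Probe sets outside the gene comparison also carried differences. Of 899 probe sets past the level filter whose annotation lists several gene symbols, 23 were at least 2-fold higher in the knockdown array and 0 were at least 2-fold lower, with a largest difference of 2.13. Of 1129 past the filter with no symbol, 13 were at least 2-fold higher and 2 lower, with a largest difference of 1.83. They are given because no gene value used them. An excess of higher values was not particular to them. By the dimmest probe set, 226 genes with 1 symbol were at least 2-fold higher and 12 lower. Whether the same uneven change of probe sets lies behind both was not tested.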

How the results depend on the processing

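With 1 array per group no replicate could be left out, and no paired analysis was possible because each group has a single array. The settings with the dimmest probe set, without _x_at probe sets, without DHCR7, relative to the median gene and on only genes with several probe sets were chosen after seeing the data. Centring on the median, quantile normalization and the lowess correction kept the 2-fold counts within 1.5 times, but relative to the median gene 32 genes were higher and 1 lower. The interferon, antigen presentation, NF-kB, cholesterol and stress response lists stayed above random lists under 13 alternatives, at percentile 99.7 or more, and the cholesterol list also without DHCR7. Of the 13, centring could not change a percentile and quantile normalization could do little. Among only genes with several probe sets the interferon list sat at the limit with the dimmest one (percentile 97.51). The alternatives for the seed of the silencing RNA were not run. The number of genes at least 2-fold higher, 19, became 37 with no level filter, 7 with a filter at the 75th percentile, 49 with the median of probe sets, 226 with the dimmest probe set, 109 at 1.5-fold and 6 at 3-fold. The number lower, 3, became 7 with no filter, 0 with the filter at the 75th percentile, 1 with a filter on the mean of both arrays, 0 with the mean of probe sets, 12 with the dimmest, 5 without _x_at probe sets, 248 at 1.5-fold and 1 at 3-fold. The L1CAM difference of -0.58 became -0.27 with the mean of its probe sets and 0.0354 with the dimmer one, since the 2 probe sets disagree. Lists above random lists numbered 10 and became 6 with the filter at the 75th percentile. Lists below numbered 2 and became 1 with unmatched random lists and 0 with the dimmest probe set. With the mean and with the median of probe sets the number was 1, but that was the silencing machinery list, and neither of the 2 stayed. These lists came inside the limits, with these medians. With no filter it was matrix proteolysis (0.0313). With the filter at the 75th percentile they were AP-1 (-0.0269), matrix proteolysis (0.0048) and NRF2 (0.0243). With the mean of probe sets they were AP-1 (0.10), basal layer (-0.0216), replication (-0.10) and NRF2 (0.0564). With the median of probe sets they were AP-1 (0.10), basal layer (-0.0219) and replication (-0.11). With the dimmest probe set they were AP-1 (0.10), mesenchymal (0.20), basal layer (-0.0006), replication (-0.0159), TGF-beta (0.13) and NRF2 (0.0718). AP-1 did so without _x_at probe sets (-0.0378) and as a mean (0.0383), the basal layer against unmatched lists (-0.28), and TGF-beta without shared genes (-0.0512). The cause was not tested. PLRG1 turned to -0.23 with the dimmest probe set. Single genes moved by more than 0.303 in 33 cases and lists inside the limits left them in 28. These were hypoxia in 8 of 13 alternatives, Notch, YAP and the silencing machinery in 3 each, the EGFR family, oxidative phosphorylation and reference genes in 2 each, and terminal differentiation, ERK output, p53, ribosomal and endothelial genes in 1 each. RMA values near background can understate changes. In this pair of arrays, though, the dimmest probe set exceeded the brightest by at least 2-fold in 229 genes and fell short by as much in 14. The differences of dim genes such as DHCR7, IGFBP3 and RSAD2 may therefore be too small or too large.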

Other observations

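The tests on transcript coverage, on the knockdown itself, on members with several probe sets and those that use the dimmest probe set or leave out _x_at probe sets were chosen only after the data were seen, and the 3 patterns were noticed in the same data that test them. Further gene groups were not called apart from random lists as deposited, though one sat exactly at the limit. Genes of the small RNA silencing machinery had a median of -0.24 over 13 members, 12 of them below 0 (percentile 7.80), and with the mean of all probe sets they lay at percentile 0.77. The median of all genes was itself below 0 (-0.11), and 5 of the 13 members lay above it. TNRC6C read -0.93, the microprocessor subunit DGCR8 -0.55, the Dicer partner TARBP2 -0.54 and TNRC6B -0.49. Hypoxia and glycolysis genes sat exactly at the upper limit, neither clearly inside nor above it (median 0.0093 over 22 members), with ERO1A at 0.43, PFKFB4 at -0.40, PGK1 at 0.38 and ALDOC at 0.32; this list lay above random lists in 8 of 13 alternatives, at percentile 97.93 after quantile normalization, 99.24 after the lowess correction and 100 with the mean of all probe sets, where its median was 0.23, and inside them in 5. Notch pathway genes had a median of 0.03 and a mean of -0.01 over 14 members (percentile 97.4), with NOTCH1 at -0.35 and JAG2 at -0.32.

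YAP and TAZ targets had a median of -0.02 and a mean of 0.14 over 19 members (percentile 86.2), with IGFBP3 at 1.37, TGFB2 at 1.06, PTPN14 at 0.65 and RBMS3 at -0.54; the median turned to 0.0244 after centring and 0.0247 with the mean of all probe sets. p53 targets went both ways: TP53I3 was at -0.88, while FAS was at 0.65 and MDM2 at 0.52, with the other MDM2 probe set at -0.19. Their median was -0.06 over 20 members (percentile 85.2), which turned to 0.0196 after the lowess correction and 0.0696 with the mean of all probe sets. Apoptosis regulators had a median of -0.01 and a mean of 0.0035 over 19 members (percentile 94.7), with BAX at -0.40 and CASP8 at 0.33; the median turned above 0 after centring and after the lowess correction. Growth factor and EGFR family genes had a median of -0.10 over 14 members (percentile 69.1), with FGFR3 at -0.64 and VEGFC at 0.36; the median turned to 0.12 with the mean of all probe sets. Wnt targets had a median of 0.01 and a mean of -0.0064 over 8 members (percentile 87.4), and the median turned to -0.0408 with the mean of all probe sets, none of the members being 1.5-fold apart (0 higher, 0 lower).

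The uneven change of probe sets of one gene is the first pattern to follow up. A bias that depends on level between the arrays predicts that a lowess correction removes it, but the ratio of genes whose dimmest probe set read at least 2-fold above the brightest to the opposite was 10.9 after the correction (197 against 18 genes). Cross-hybridisation of the _x_at kind of probe set predicts that the pattern vanishes without them, but the ratio was then 20.6; that of other kinds was not tested and stays open. Unequal coverage of transcripts in the 2 RNA samples, as from RNA integrity or the reach of labelling, stays open: the dimmer probe set was favoured in 68.2% of genes, but that share restates the pattern, and the positions of probes along transcripts, which would test it, were not used here. An effect of the L1CAM knockdown and unequal coverage cannot be told apart with 1 array per group.

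The disagreement of the 2 L1CAM probe sets may be part of the same pattern. The dimmer L1CAM probe set exceeded the brighter one by 0.62, which lies at percentile 69.3 of the gaps in 1344 other genes with a like difference in level. Those gaps had a median of 0.37 and a central 95% from -0.68 to 1.31. The arrays leave the depth of the knockdown open, and no biological explanation of the gap was tested.

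The higher interferon, antigen presentation and NF-kB lists are the third pattern. The choice of probe set predicts that at least 1 of the 3 lists falls among random lists under another gene summary, and the lowest of their percentiles was 99.94 over 3 other summaries. That test was diluted, because 13 of 23, 1 of 14 and 8 of 16 members had 1 probe set past the filter and could not change with the median or the dimmest probe set. Among only the genes with several, the lowest percentile was 97.51 (interferon, dimmest probe set), which 10000 random lists cannot part from the limit, while the same members against all genes lay at 99.66, so the choice of probe set stays open for the interferon list. The L1CAM knockdown, a response to the infected virus or hairpin RNA, and a difference between the cultures all stay open, because with 1 array per group they cannot be told apart.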
